A study of Danio rerio with 9 samples.

How the data were processed

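Alternative last exons were measured by RNA-seq in 9 libraries of zebrafish embryos, in 3 groups of 3. Per the labels, 6 libraries came from embryos injected at the first-cell stage with 200 pg of an mRNA for translating ribosome affinity purification (TRAP), a method that pulls down tagged ribosomes with the RNA bound to them. These embryos were raised at 28.5 °C, and 100 ng of RNA from each of 24, 48 and 72 hours post fertilization (hpf) was pooled. The pull-down and the flow-through, the unbound remainder, gave 3 libraries each. The other 3 libraries came from untreated wild-type embryos at 24 hpf. Groups were taken from the sample titles. Nothing in the labels says that replicates came from separate clutches, so p-values measure the spread between these libraries, which may be technical.

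The deposited table lists 1264 assembled transcripts that end in an alternative last exon, belonging to 1188 splicing events and 1085 gene identifiers. Per the file headers, each transcript has a TPM value in each library. Per the file headers, each event has a deposited PSI (percent spliced in), given as a fraction from 0 to 1 and multiplied here to percent. Transcripts of the same event carry the same PSI. The submitters' processing notes name HISAT2 2.2.1 and StringTie 3.0.0, and the builds GRCz11 and danRer10, with no roles. Which of these builds the table's coordinates use is not given in the sources used here, so coordinates are printed as the table gives them. The tool that computed PSI and the filter that chose the transcripts are also not given in the sources used here. No read counts were used here, so the depth is unknown and no interval that needs read numbers is given. The TPM values of the listed transcripts summed to between 407 and 1345 per library. Gene names are those of the deposited table. Of its 1085 identifiers, 1059 were also found in a separate reference table of gene names, from which no name was taken. The 41 transcripts without a name are called by their identifier.

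Transcript level was tested with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided) on log2(TPM + 0.5). Transcripts with at least 0.5 TPM in at least 3 of the 6 libraries compared were tested. PSI was tested with limma (eBayes without trend, two-sided) in percentage points, for events whose PSI was not constant over the 6 libraries. Each of the 3 pairwise comparisons used the libraries of its own groups, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. A log2 difference is on the log2(TPM + 0.5) scale, which understates the change of low transcripts. Where a group is at 0 in all 3 libraries, it is called listed at 0 and no fold is given. Library totals were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot go below p = 0.1. Between 132 and 272 transcripts were tested, under the 1000 set for a camera test. Gene lists were therefore described by the number of members past the threshold. Lists with at least 5 tested genes also had an exact two-sided Fisher test against the other tested genes, with several transcripts of a gene counted as 1 gene by the highest mean TPM.

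These choices, the alternatives and the gene lists were fixed before the data were examined, and added alternatives are named as such. The 14 lists were axon guidance and adhesion receptors, synapse and vesicle release, ion channels and neurotransmitter receptors, cytoskeleton and transport, RNA binding and splicing, and chromatin and transcription. The others were neural, muscle, skin and matrix, blood and vessel, and yolk, liver, gut and kidney markers, ribosomal proteins and translation factors, mitochondrial respiration, and genes of earlier cryptic last exon interest. Named transcripts were those 10 with the largest increase and 10 with the largest decrease past the threshold without overlap between the libraries, and the 5 with the highest mean TPM past it. Where fewer than 10 passed, those with the smallest p filled the 10 and are said not to pass. Named events followed the same rule, joined by the 15 with the highest wild-type PSI, up to 4 members of each list, and every member of the list of earlier interest. Exceptions, chosen after their values were seen, are named as such.

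The alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 2 TPM, centring of each library on its median, all 9 libraries in one fit, the replicate number as a block, limma without or with trend, and each library left out. For PSI they were a logit scale with 1 percentage point added, an event TPM filter of 0.5, and events with a mean PSI between 5 and 95%. A planned comparison of short with full-length isoforms was not run, since the table does not pair these forms. On simulated data with 132 transcripts for pull-down against flow-through, 0% of 2-fold, 30.8% of 4-fold and 85.7% of 8-fold changes were recovered, with 0 false calls. These shares rested on 13, 13 and 7 changed transcripts in a single simulation. With 272 transcripts for wild type against flow-through, the shares were 57.7%, 94.4% and 100%, with 0 false calls. With 260 transcripts for pull-down against wild type, they were 59.3%, 88.2% and 90.5%, with 1 false call. The simulated noise was normal on the log2 scale, with spreads shuffled among transcripts and without the zeros of the data. The transcript shares are therefore approximate. For PSI, simulated with an assumed 20 reads per event, 50.0% of 25-point and 92.1% of 50-point changes were recovered among the 298 events of pull-down against flow-through. These shares were 60.0% and 93.1% among the 628 events of wild type against flow-through, with 5 false calls. They were 53.2% and 94.5% among the 599 events of pull-down against wild type, also with 5 false calls. These PSI simulations held read sampling only, with no other spread between libraries. In the data, the median 95% confidence interval reached 43.5 percentage points to either side for pull-down against flow-through. The PSI shares simulated for that comparison are therefore too high for these data. The interval reached 5.34 points for wild type against flow-through and 4.98 for pull-down against wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.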

Results

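Transcripts that end in an alternative last exon were measured in zebrafish embryos, in RNA bound to tagged ribosomes (pull-down), in the unbound RNA of the same injected embryos pooled over 24, 48 and 72 hpf (flow-through), and in untreated wild-type embryos at 24 hpf, with 3 libraries each. Wild-type embryos held most of these transcripts: 852 of the 1264 were above 0 TPM in all 3 wild-type libraries, against 169 in flow-through and 96 in pull-down. Single libraries held 417, 296 and 442 in flow-through, 441, 180 and 253 in pull-down, and 1076, 1024 and 1049 in wild type. A count over all 3 is thus limited by the sparsest library. At 0.5 TPM or more, the mean numbers were 152 in flow-through, 160 in pull-down and 319 in wild type. Of the 1264, 625 were listed at 0 in all 3 flow-through libraries, 715 in all 3 pull-down libraries and 30 in all 3 wild-type libraries. The listed transcripts summed to 407, 469 and 424 TPM in the flow-through libraries, 483, 465 and 478 TPM in pull-down, and 1238, 1173 and 1345 TPM in wild type. The wild-type sum was 2.89 times that of flow-through, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and 0.191 after Benjamini-Hochberg adjustment over 21 such comparisons. Across transcripts, which are not independent replicates, Spearman's rho between libraries of a group was 0.470 to 0.532 in flow-through, 0.423 to 0.466 in pull-down and 0.666 to 0.697 in wild type. Between a pull-down and a flow-through library it was 0.390 to 0.503. By this measure the pull-down libraries were no more alike among themselves than they were to flow-through. The last exons had a median width of 243 bases, from 21 to 8632. Read numbers were not used here, so the depth of each library is unknown.

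The deposited PSI of these last exons in untreated embryos was low for most events. It was also 0 for 50.6% of wild-type values at 5 TPM or more, so low inclusion is not shown. Of the 1188 events, 131 had a PSI above 0 in all 3 wild-type libraries, 22 in all 3 flow-through libraries and 7 in all 3 pull-down libraries. A mean PSI of at least 10% was reached by 112 events in wild type, 136 in flow-through and 114 in pull-down. A mean PSI of at least 50% was reached by 47, 30 and 13 events. With only 22 flow-through and 7 pull-down events above 0 in all 3 libraries, most of the 136 and 114 rested on fewer than 3. In wild type, 18 events stood at 100% in all 3 libraries. They included events in orc2, a subunit of the origin recognition complex, pax3a, a transcription factor of the dorsal neural tube and neural crest, porcn, an acyltransferase that modifies Wnt proteins, and slc12a1, an ion cotransporter. The orc2 event was at 100% in every library of all 3 groups, while its transcript was at 10.002 ± 1.11 TPM in wild type, 1.03 ± 0.514 in flow-through and 4.37 ± 1.54 in pull-down (SD, n = 3 each). The porcn event was at 0% in flow-through and pull-down, where its transcript was listed at 0. Only 54 wild-type events had a mean PSI of at least 10% when at least 0.5 TPM was asked for in all 3 libraries.

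**Figure D1:**
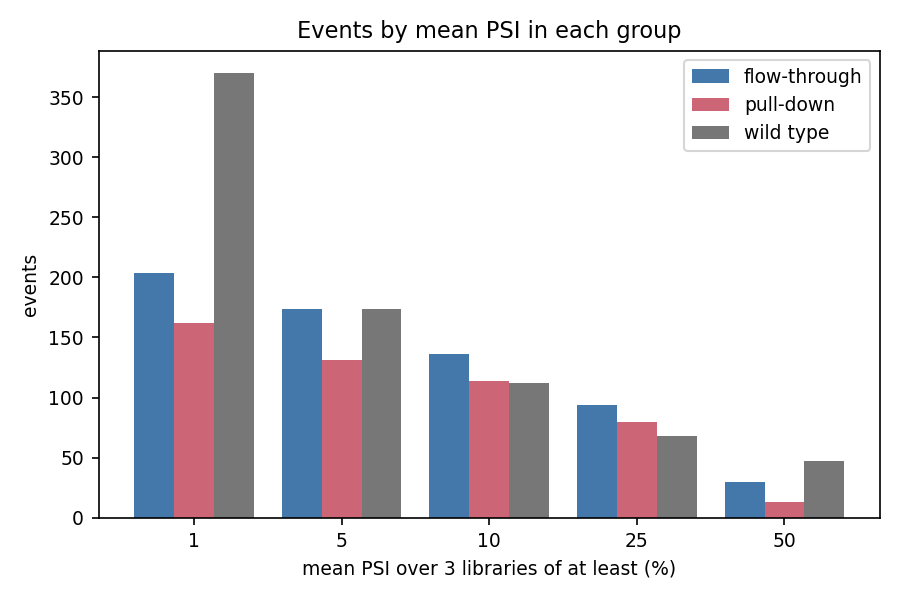
Number of events (vertical axis) with a mean PSI over 3 libraries of at least 1, 5, 10, 25 or 50% (horizontal axis) in each group. Wild type had 370 events at 1% or more against 204 in flow-through and 162 in pull-down, and 112, 136 and 114 events at 10% or more. At 10% or more, most flow-through and pull-down events were above 0 in fewer than 3 libraries.

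The comparison of pull-down with flow-through asked which alternative last exon transcripts were recovered with ribosomes. No pull-down from uninjected embryos is among the libraries, so other carry-over into the pull-down was not separated from ribosome binding. A transcript of LIMD2, a LIM domain gene, was far higher in the pull-down, at 38.4 ± 5.22 TPM against 2.34 ± 0.928 TPM in flow-through (SD, n = 3 each), and at 17.1 ± 2.75 TPM in wild type. A pair of transcripts of col7a1l, a gene named after type VII collagen, moved in opposite directions. One, MSTRG.47463.2, rose from 5.51 ± 1.43 to 20.6 ± 1.84 TPM (wild type 32.1 ± 1.99), and the other, MSTRG.47463.8, was at 12.2 ± 1.67 TPM in flow-through and listed at 0 in all 3 pull-down libraries (wild type 0.0403 ± 0.01002). These transcripts have different gene identifiers, ENSDARG00000069692 and ENSDARG00000093135, and the same last exon, chromosome 4, 15948460 to 15949244, so the split of reads between them is uncertain. A transcript of inpp4b, a phosphoinositide phosphatase gene, fell from 10.5 ± 2.14 to 2.40 ± 0.585 TPM (wild type 1.81 ± 1.58). The PSI of the events of these 4 transcripts was 0% in all 3 libraries of both fractions, the lowest value PSI can take. It does not show whether their inclusion changed. In wild type the PSI was 92.1 ± 3.72% for LIMD2 and 0% in all 3 libraries for the other 3.

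These 4 transcripts, of 3 genes by name, were the only ones past the limma threshold among 132 tested. LIMD2 (MSTRG.40142.5, ENSDARG00000112015, chromosome 24, 19998357 to 20002666) had a log2 difference of 3.81 (SE 0.29) and a limma adjusted p of 8.64e-05. The log2 difference of col7a1l MSTRG.47463.2 was 1.84 (SE 0.26, limma adjusted p 0.00554), and MSTRG.47463.8 had a limma adjusted p of 8.64e-05. For inpp4b (MSTRG.2417.11, chromosome 1, 53220199 to 53220391) the log2 difference was -1.92 (SE 0.31, limma adjusted p 0.00931). All 4 separated the 6 libraries without overlap, as did 36 of the 132 tested (27.3%, against 10% by chance), and 26 had an unadjusted p under 0.05. The inpp4b call was lost with no filter, with all 9 libraries in one fit, and without flow-through replicate 1 or 2, with limma adjusted p values of 0.0548, 0.0936, 0.119 and 0.0707, within a range of 0.00318 to 0.119 over all alternatives. The number of calls was 8 with all 9 libraries in one fit, 2 without flow-through replicate 2 and 11 without pull-down replicate 1, and 13 among transcripts above 0 in all 6 libraries, an alternative added after seeing the data.

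Among transcripts that did not pass, prc1a, a regulator of cytokinesis, was at 0.409 ± 0.198 TPM in flow-through and 2.42 ± 0.571 TPM in pull-down (limma adjusted p 0.0966). It passed with all 9 libraries in one fit (limma adjusted p 0.0116) and with at least 2 TPM (0.0367). The orc2 values had a limma adjusted p of 0.106, and 0.0197 with all 9 libraries in one fit. Transcripts of klc4, a kinesin light chain, were at 7.93 ± 0.425 and 3.91 ± 0.721 TPM, and those of pbrm1, a chromatin remodelling subunit, at 8.46 ± 2.29 and 2.82 ± 1.80 TPM (limma adjusted p 0.140 for each). The klc4 difference passed with all 9 libraries in one fit (limma adjusted p 0.0325), with at least 2 TPM (0.0367) and without pull-down replicate 1 (0.0460, with the filter applied again only). That of pbrm1 passed without pull-down replicate 1 both ways (limma adjusted p 0.0258, and 0.0318 with the tested transcripts kept). Among transcripts above 0 in all 6 libraries, the added alternative, all 4 passed (limma adjusted p 0.0102 for prc1a, 0.0216 for orc2, 0.0461 for klc4 and 0.0420 for pbrm1). Transcripts of pcdh11, a protocadherin gene, at 2.25 ± 0.295 and 0.635 ± 0.0996 TPM (limma adjusted p 0.140), and of pdcd6, at 0.125 ± 0.0917 and 1.12 ± 0.498 TPM (0.150), did not pass either. Both passed with all 9 libraries in one fit (limma adjusted p 0.0175 and 0.0441) and in the added alternative (0.0216 and 0.0326). Those of capns1a, cmah and b4galt1 passed only in the latter (limma adjusted p 0.0420, 0.0499 and 0.0499). That of ENSDARG00000116271 passed only without flow-through replicate 1 (limma adjusted p 0.0424). Of the prespecified lists, 0 members passed, over all transcripts tested or adjusted over the list alone. The tested members were 2 axon guidance and adhesion genes, ncam1a and plxna3, 3 cytoskeletal genes, diaph2, dclk1a and dclk1b, 2 chromatin genes, znf536 and satb1a, and 2 matrix genes, col16a1 and col14a1a. The muscle list had casq2, the ribosomal list rpl29, and the mitochondrial list sdhc. It passed without pull-down replicate 1 (limma adjusted p 0.0448 against 0.351) only where the filter was applied again, and not with the tested transcripts kept. The neural adhesion gene ncam1a, also the 1 tested gene of earlier cryptic last exon interest, was at 1.22 ± 0.286 TPM in flow-through and 0.837 ± 0.951 TPM in pull-down. The median 95% confidence interval of a difference reached 1.23 to either side on the log2 scale, and for 7 of the 132 transcripts it lay within ±1.

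In PSI, 2 events passed the limma threshold between pull-down and flow-through. Of the 10 splits of the 6 libraries, 3 reached that number, the real one included, so it does not stand out from other groupings. The last exon of antxr2a (AS22817, chromosome 5, 39454657 to 39457239), a gene for a matrix-binding receptor, had a PSI of 0% in all 3 flow-through libraries and 100% in all 3 pull-down and all 3 wild-type libraries. Its transcript was present in both fractions, at 1.80 ± 0.512 TPM in flow-through and 2.30 ± 1.36 TPM in pull-down (SD, n = 3 each). The last exon of mocs1 (AS07683, chromosome 17, 41352374 to 41353208), a gene of molybdenum cofactor synthesis, went the other way, from 100% in all 3 flow-through libraries to 0% in all 3 pull-down libraries, and was at 9.0 ± 7.77% in wild type. Its transcript was scarce, at 0.720 ± 0.512 TPM in flow-through and 0.103 ± 0.178 TPM in pull-down, where 1 of the 3 libraries was above 0 TPM, so its PSI of 0 there cannot be read as lower inclusion. Both had a limma adjusted p of 1.31e-04 among 298 events tested, of which 7 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 7 of the 298 (2.35%, with ties counted as overlap). A share of 10% by chance holds only without ties, so it does not apply to these PSI values. Events in cpped1 (3.33 ± 5.77% in flow-through, 82.8 ± 29.8% in pull-down, limma adjusted p 0.430) and in kmt2cb, a histone methyltransferase gene (63.5 ± 31.8% and 0% in all 3 libraries, limma adjusted p 0.622), did not pass. The libraries of each group were identical for both called events, so their SE rests on the spread of other events, and with trend neither passed (limma adjusted p 0.116, the highest of a range from 3.07e-07 for antxr2a and 7.61e-06 for mocs1). Calls numbered 6, 4 and 5 without flow-through replicate 1, flow-through replicate 3 and pull-down replicate 1, and 1 with the event TPM filter, where mocs1 was not tested.

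**Figure D2:**
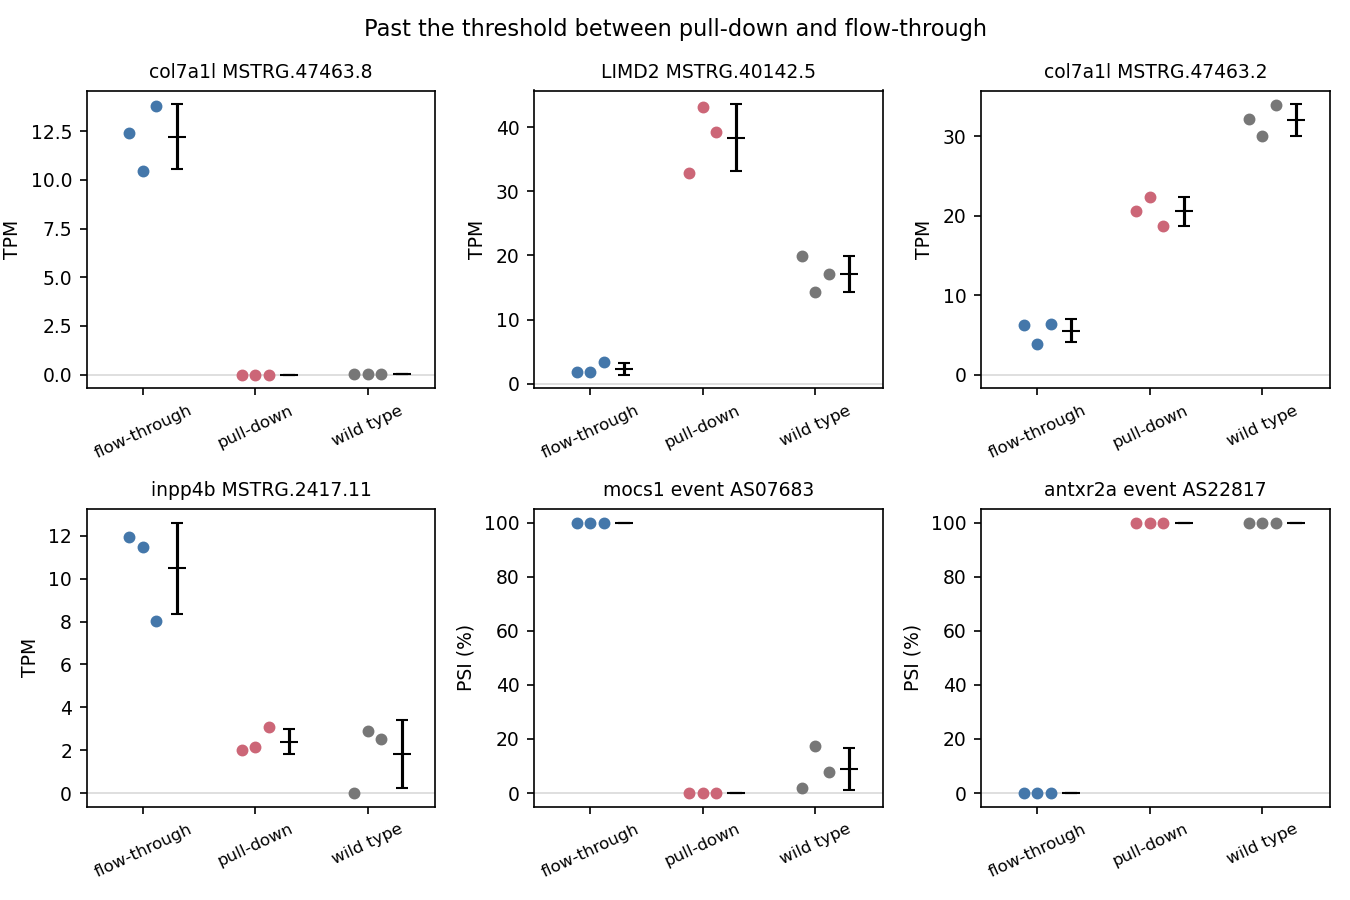
TPM of the 4 transcripts and PSI (%) of the 2 events past the limma threshold between pull-down and flow-through, with wild type beside them; points are libraries and black bars the mean ± SD (n = 3). LIMD2 averaged 2.34 TPM in flow-through and 38.4 in pull-down, col7a1l MSTRG.47463.8 was listed at 0 in pull-down, and mocs1 and antxr2a went between 0 and 100% in opposite directions.

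Wild-type embryos at 24 hpf were set beside flow-through, libraries that differ in age, injection and fraction together. Most tested transcripts were higher in wild type. Those of ADGRL2, an adhesion G protein-coupled receptor, were at 17.0 ± 0.710 TPM in wild type and 0.136 ± 0.236 TPM in flow-through, and those of rplp0, a ribosomal stalk protein, at 10.3 ± 1.31 and 0.116 ± 0.1003 TPM (SD, n = 3 each). Transcripts of prc1a rose from 0.409 ± 0.198 to 16.7 ± 3.54 TPM, those of lars1a, a leucyl-tRNA synthetase, from 0.337 ± 0.425 to 12.8 ± 1.38 TPM, and those of cdk4, a cell cycle kinase, from 7.11 ± 1.25 to 27.9 ± 5.29 TPM. Lower in wild type were tgm2b, a transglutaminase (5.86 ± 3.29 TPM in flow-through and 0.322 ± 0.0627 in wild type), nptx1l, a neuronal pentraxin (2.30 ± 0.444 and 0.0657 ± 0.0691 TPM), myhz1.1l, named after a fast muscle myosin heavy chain (2.21 ± 0.625 and 0.312 ± 0.0495 TPM), and sdhc, a succinate dehydrogenase subunit (1.21 ± 0.105 and 0.110 ± 0.0696 TPM).

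By limma, 210 of 272 tested transcripts, in 198 genes, passed the threshold, 183 higher and 27 lower in wild type. At least 0.5 TPM in all 3 libraries, which alone meets the filter, was reached by 235 transcripts in wild type and 75 in flow-through. The tested transcripts therefore lean towards those present in wild type. Among transcripts above 0 in all 6 libraries, an alternative added after seeing the data, 73.9% of calls were higher. Of the 183, 46 were listed at 0 in all 3 flow-through libraries, among them tmem108 (10.4 ± 0.895 TPM in wild type, limma adjusted p 1.08e-05) and mfsd11 (7.32 ± 0.136 TPM). The largest log2 differences were 4.84 for ADGRL2 (SE 0.27, limma adjusted p 2.11e-05), 4.66 for cnksr3 (SE 0.21, limma adjusted p 1.61e-05) and, among those lower, -4.55 for col7a1l MSTRG.47463.8 (SE 0.16, limma adjusted p 1.08e-05). Among the transcripts with the highest mean TPM, zgc:63587 went from 6.68 ± 1.68 to 77.1 ± 5.61 TPM, psip1b from 16.8 ± 4.63 to 57.4 ± 6.59 TPM and unm_hu7910 from 51.0 ± 10.8 to 18.2 ± 4.56 TPM. The groups did not overlap for 218 of the 272 (80.1%, against 10% by chance). That 10% does not allow for how the listed transcripts were chosen, which is not given in the sources used here. The median log2 difference of all tested transcripts was 1.43, and with each library centred on its median 154 passed, 72 higher and 82 lower, so that 87.1% of calls were higher before centring and 46.8% after. Centring ended the call of psip1b (log2 difference 0.28, limma adjusted p 0.165), as did all 9 libraries in one fit (0.117), and inpp4b, lower in wild type, lost its call with a pseudocount of 0.1 (limma adjusted p 0.0600) and without flow-through replicate 1 (0.05003). Without wild-type replicate 1, 2 or 3, where 145, 146 and 154 transcripts met the filter, 68, 69 and 69 passed. Of these calls 69.1%, 71.0% and 68.1% were higher. With no filter 338 passed.

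**Figure D3:**
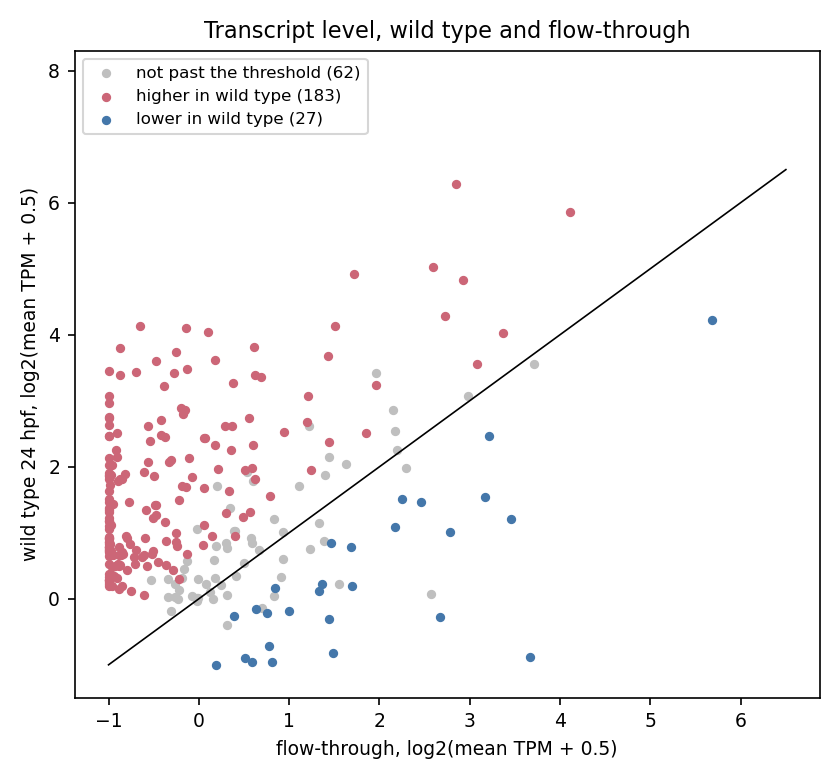
Mean transcript level of the 272 tested transcripts in flow-through (horizontal) and wild type (vertical), both as log2(mean TPM + 0.5), with a line of equal level. Points above the line include 183 past the limma threshold, and 27 past it lie below.

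All 5 tested axon guidance and adhesion genes were higher in wild type: efnb3a, an ephrin-B ligand (9.96 ± 1.52 TPM, flow-through 0.0440 ± 0.0762), plxna3, a semaphorin receptor (4.93 ± 0.112, flow-through 0.549 ± 0.127), nrcama, sema3ab and ncam1a. With centring, efnb3a and plxna3 stayed higher, ncam1a turned lower (log2 difference -0.73), and nrcama and sema3ab did not pass. All 5 tested skin and matrix genes were higher, among them col16a1 (9.17 ± 2.75 TPM, flow-through 0.801 ± 0.300) and col14a1a (MSTRG.17583.7, 5.03 ± 0.801 TPM, listed at 0 in flow-through), and with centring col16a1, col14a1a and frem1b passed and the other 2 did not. Beside each list 191 of 241 other genes were called, and even 5 of 5 gives an exact Fisher p of 0.586 (0.782 after adjustment over 4 tests), so more frequent calls in these lists could not have been shown. Of 4 chromatin and transcription genes, pax3a and pax7b were higher and znf536 lower in wild type, and satb1a did not pass, while with centring pax3a stayed higher, znf536 and satb1a were lower and pax7b did not pass. Of 4 cytoskeletal genes, diaph2, an actin-nucleating formin, was higher (8.90 ± 1.98 TPM, flow-through 3.38 ± 2.43) and macf1a, dclk1a and dclk1b did not pass. With centring, diaph2 did not pass and dclk1a and dclk1b were lower.

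The 1 tested synaptic gene, cadps2, and the 1 tested RNA-binding gene, msi1b, were higher in wild type, and neither passed with centring, where the msi1b difference turned to -0.26. The ribosomal list had rplp0 higher and rpl29 lower, the mitochondrial list had sdhc lower, each with and without centring, and the muscle gene casq2 did not pass. The ion channel list (8 genes in the table) and the neural markers (2 genes) had no tested member, and the blood and vessel list and the yolk, liver, gut and kidney list had 0 genes in the table. Adjusted over the list alone, 5 axon guidance, 5 matrix, 3 chromatin, 2 ribosomal, 1 mitochondrial, 1 synaptic, 1 RNA-binding and 0 cytoskeletal genes passed, and 0 of the muscle list. Of the genes of earlier interest, ncam1a passed over the list alone too, at 2.45 ± 0.736 TPM in wild type, while epha4b (0.305 ± 0.102 TPM) and immp2l (0.0633 ± 0.0978 TPM) were below the filter. The calls of ncam1a (without flow-through replicate 1 or 2 or wild-type replicate 2 or 3), diaph2 (without flow-through replicate 1 or 3 or wild-type replicate 1 or 3) and rpl29 (without any library but flow-through replicate 2) were lost, with limma adjusted p values of 0.0627 to 0.164, 0.0528 to 0.0721 and 0.0800 to 0.242. They were also lost with no filter (limma adjusted p 0.0651, 0.0503 and 0.0906) and with all 9 libraries in one fit (0.213, 0.0548 and 0.161), and that of rpl29 with a pseudocount of 0.1 (0.0588).

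PSI was higher in wild type than in flow-through for most of the events that differed, though many of their transcripts were scarce or absent in flow-through. Events in dph1, a gene of diphthamide synthesis, nod1, an innate immune receptor, mfsd11, antxr2a and porcn were at 0% in all 3 flow-through libraries and 100% in all 3 wild-type libraries. The mocs1 event fell by 91.0 percentage points, and lower values were also found for mtor, the growth-regulating kinase (85.2 ± 25.6% in flow-through, 2.47 ± 0.416% in wild type, beside only 0.00667 ± 0.0115 and 0.0880 ± 0.0731 TPM), and gnmt, glycine N-methyltransferase (19.5 ± 4.996% and 0.50 ± 0.866%). By limma, 36 of 628 events passed, 31 higher and 5 lower, and all 31 were at 0% in the 3 flow-through libraries. There the transcripts of 7 of the 31 were listed at 0 TPM in all 3 libraries, among them mfsd11 and porcn, and those of 12 more in 1 or 2. Only 7 averaged at least 0.5 TPM, among them antxr2a at 1.80 ± 0.512, while nod1 was at 0.116 ± 0.0840 and dph1 at 0.206 ± 0.182 TPM. In flow-through a PSI of 0 went with 98.2% of values at 0 TPM, 79.5% of those above 0 to 0.5 TPM, 74.4% at 0.5 to 2 TPM, 65.9% at 2 to 5 TPM and 53.6% at 5 TPM or more. A PSI of 0 was thus the most frequent value for present transcripts too, that of antxr2a included, and beside an absent transcript it cannot be read as lower inclusion. The libraries did not overlap for 88 of the 628 (14.0%, with ties counted as overlap). Ties put the share by chance below 10%, and it was not computed. The limma adjusted p was 4.33e-09 for dph1 and 3.11e-04 for mocs1. For 7 of the 36 called events, dph1 included, the libraries of each group were identical. Their SE rests on the spread of other events. Over all settings the limma adjusted p of dph1 ran from 1.70e-13 to 1.56e-04. The events in mtor, gnmt, unm_hu7910 and csrp2, the other 4 lower, lost their calls with the replicate block (limma adjusted p 0.204, 0.141, 0.157 and 0.157). So did mtor without any library but flow-through replicate 3 (0.109 to 0.130), gnmt without any but flow-through replicate 2 (0.0537 to 0.101), csrp2 without any but wild-type replicate 1 (0.0576 to 0.130) and unm_hu7910 without flow-through replicate 2 or 3 (0.0676 and 0.0576). With all 9 libraries in one fit and with trend, the calls of mtor (limma adjusted p 0.194 and 0.0502), gnmt (0.0514 and 0.106) and csrp2 (0.645 and 0.389) were lost as well, and on the logit scale that of mtor (0.0503). Calls numbered 18 with the replicate block, 19 with trend and 16 among events above 0 TPM in all 6 libraries, an alternative added after seeing the data.

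Between pull-down and wild type, libraries that again differ in age, injection and fraction, most transcripts were lower in the pull-down. Those of b4galt1, a galactosyltransferase, were at 0.794 ± 0.682 TPM in pull-down and 29.7 ± 6.77 TPM in wild type, and zgc:63587 was at 3.70 ± 0.499 and 77.1 ± 5.61 TPM (SD, n = 3 each). Higher in pull-down were tgm2b (2.97 ± 1.25 and 0.322 ± 0.0627 TPM), unm_hu7910 (54.5 ± 2.93 and 18.2 ± 4.56 TPM), LIMD2 (38.4 ± 5.22 and 17.1 ± 2.75 TPM) and cd276, an immune checkpoint gene (2.97 ± 0.872 and 0.672 ± 0.165 TPM). By limma, 186 of 260 transcripts passed, 15 higher and 171 lower in pull-down (8.06% higher), around a median log2 difference of -1.48. The groups did not overlap for 193 of the 260 (74.2%). With centring 107 passed, 66 higher and 41 lower (61.7% higher), and col7a1l MSTRG.47463.2, lower by -0.63 (limma adjusted p 0.00500), turned higher by 1.21. Log2 differences were -4.70 for b4galt1 (SE 0.50, limma adjusted p 2.97e-04), 2.02 for tgm2b (SE 0.31, limma adjusted p 0.00145) and 1.15 for LIMD2 (SE 0.18, limma adjusted p 0.00140). Without wild-type replicate 1, 2 or 3, calls numbered 46, 45 and 47 under the filter. Among transcripts above 0 in all 6 libraries, the added alternative, 29.4% of calls were higher in pull-down.

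Of the lists, 4 of 5 axon guidance genes (exact Fisher p 1) and 5 of 5 matrix genes (exact Fisher p 0.326) were lower in the pull-down than in wild type, numbers too small to show more frequent calls. With centring only efnb3a and plxna3 of the first and col16a1 of the second stayed lower. Lower as well were pax3a and pax7b of 3 chromatin genes, diaph2 of 3 cytoskeletal genes, cadps2, msi1b and rplp0, while rpl29 was higher. The rpl29 call was lost with no filter (limma adjusted p 0.0708) and without any 1 of the wild-type replicates (0.0746 to 0.155), and ncam1a passed only without pull-down replicate 3 (limma adjusted p 0.00895 against 0.0709), with all 9 libraries in one fit (0.0373) or with the replicate block (0.0415). With centring, pax7b, rplp0 and pax3a (MSTRG.29258.2) stayed lower, diaph2, cadps2 and msi1b did not pass, and dclk1a, dclk1b, satb1a and casq2 were higher. In PSI, 34 of 599 events passed by limma, 2 higher and 32 lower in pull-down. The libraries did not overlap for 75 of the 599 (12.5%, with ties counted as overlap, which puts the share by chance below 10%). Of the 32, the transcripts of 13 were listed at 0 TPM in all 3 pull-down libraries, and 10 averaged at least 0.5 TPM there. The event of dclk1b, a doublecortin-like kinase, was at 100% in all 3 pull-down libraries and 9.57 ± 2.25% in wild type (limma adjusted p 1.75e-06), and that of unm_hu7910 was at 100% in all 3 and 93.97 ± 1.14%. The latter lost its call with the replicate block (limma adjusted p 0.148) and without pull-down replicate 2 or 3 (0.0688 and 0.0650). The events of dph1, nod1, mfsd11, porcn and pax3a were at 0% in all 3 pull-down libraries and 100% in all 3 wild-type libraries, and that of pax3a did not pass with all 9 libraries in one fit (limma adjusted p 0.103). In pull-down their transcripts were at 0.975 ± 0.383 TPM for dph1, 0.120 ± 0.105 for nod1, 0.764 ± 0.903 for mfsd11, 0 for porcn and 0.261 ± 0.231 for pax3a. A PSI of 0 went with 98.5% of pull-down values at 0 TPM, 84.5% above 0 to 0.5 TPM and 76.8% at 0.5 to 2 TPM, so it cannot be read as lower inclusion where the transcript was absent. The LIMD2 event, at 38.4 ± 5.22 TPM in pull-down, was among the 32 lower ones (limma adjusted p 1.09e-05). A PSI of 0 also went with 68.5% of pull-down values at 2 to 5 TPM and 68.9% at 5 TPM or more. It was thus the most frequent value for present transcripts too, and for LIMD2 it does not by itself show lower inclusion.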

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

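Alternatives that required values above 0 in all 6 libraries, and those that left out a library but kept the tested transcripts, were chosen after seeing the data; the others were planned. Among named transcripts and events over all alternatives, 2002 transcript values kept direction and side of the threshold, 98 lost it, 34 gained it and 45 changed direction. For PSI, 653 kept both, 38 lost it, 28 gained it and 0 changed direction. Features that an alternative no longer tested are not in these numbers, so calls lost through a filter are not counted as lost. Most named features were also picked as the largest calls or smallest p values in these data, so the numbers overstate how well calls held. The unknown depth leaves open which zeros are too few reads. Except where a reason is given, the cause was not tested. The planned comparison of short with full-length forms and camera with an estimated correlation were not run.

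For pull-down against flow-through, the 4 called transcripts became 8 with all 9 libraries in one fit and 13 among the 66 transcripts above 0 in all 6 libraries. Leaving out a library gave 2 to 11, the lowest without flow-through replicate 2 and the highest without pull-down replicate 1. With the tested transcripts kept it gave 3 to 8, the highest again without pull-down replicate 1. The 2 called events became 1 with the event TPM filter, 0 with trend (7 had an unadjusted p under 0.05 in limma without trend) and 1 among events above 0 TPM in all 6 libraries, where 62 and 32 events were left for the first and last, and 2 to 6 without a library. For wild type against flow-through, the 210 transcripts became 338 with no filter, 98 with at least 2 TPM and 88 above 0 in all 6 libraries, where 1256, 114 and 121 were tested. Leaving out a library gave 68 to 205. The low end came from the filter, which needs 3 libraries when 2 of wild type remain, since with the tested transcripts kept it was 191 to 217. The 36 events became 18 with the replicate block, 19 with trend and 16 above 0 TPM in all 6 libraries, and 30 to 50 without a library. For pull-down against wild type, the 186 transcripts became 333 with no filter, 94 with at least 2 TPM, 107 with centring and 51 above 0 in all 6 libraries, 45 to 192 without a library, and 161 to 195 with the tested transcripts kept. The 34 events became 53 on the logit scale, 21 with the replicate block and 13 above 0 TPM in all 6 libraries, and 28 to 49 without a library. The 112 wild-type events at 10% or more became 54 with at least 0.5 TPM in all 3 libraries.

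With centring, these log2 differences turned for wild type against flow-through: diaph2 -0.063, macf1a -0.84, dclk1b -1.27, dclk1a -1.41, msi1b -0.26, casq2 -0.90, lamc1 -0.11 and ncam1a -0.73. For pull-down against wild type they were col7a1l MSTRG.47463.2 1.21, cadps2 0.18, dclk1a 1.65, dclk1b 1.77, msi1b 0.70, satb1a 1.66, lamc1 0.47, col5a3a 0.34 and ncam1a 0.46. These follow from centring itself, which moves the median of the tested transcripts to 0, so they are differences relative to each library's median and not folds. In TPM, cadps2, lamc1 and col5a3a were listed at 0 in all 3 pull-down libraries and lamc1 in all 3 flow-through libraries, so they were not higher there than in wild type, and lamc1 was not lower in wild type. List members not past the threshold, with differences near 0, also turned without 1 library. Over the left-out libraries, pull-down against flow-through gave dclk1b -0.20 to 0.44, dclk1a -0.41 to 0.12, satb1a -0.46 to 0.088 and col14a1a -0.22 to 0.44, which was also negative at -0.13 and -0.18. Wild type against flow-through gave dclk1b -0.00157 to 0.38 and dclk1a -0.071 to 0.18, which was also negative at -0.00530. Pull-down against wild type gave dclk1a -0.49 to 0.033, dclk1b -0.42 to 0.22, which was also positive at 0.15, and casq2 -0.27 to 0.58, which was also negative at -0.00145. The turned values were the same with the tested transcripts kept.

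Groups share replicate numbers in the labels, but same-numbered libraries did not deviate together: 0 of the 3 pairs in any comparison had a correlation over 0.1, from -0.141 to 0.0808 over both measures. With the replicate number as a block, the calls numbered 4 and 2 for pull-down against flow-through, 205 and 18 for wild type against flow-through, and 182 and 21 for pull-down against wild type, for transcripts and events.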

Other observations

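The tests of the wild-type excess, of the col7a1l sum, of too few reads at an event and of the number of events in the pull-down were chosen only after the result was seen. For depth, a first choice of transcripts by their mean over both compared groups, which had excluded it, was dropped because the change itself raises that mean. The criteria for the width of the last exon, for the covariance and for the number of events were also made stricter after the values were seen, so that an overlap or a wide interval excludes nothing.

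Some alternative last exon transcripts were present in every library: 68 of the 1264 were above 0 TPM in all 9 libraries and 37 reached at least 0.5 TPM in all 9. Chosen after their values were seen, atrxl stood at 12.6 ± 3.06 TPM in flow-through, 17.4 ± 2.95 in pull-down and 11.3 ± 0.168 in wild type, and syngr1a, a synaptogyrin gene, at 6.12 ± 0.410, 4.79 ± 1.59 and 19.0 ± 0.821 TPM (SD, n = 3 each). The gene ENSDARG00000112301 had 3 transcripts of 1 event that moved apart in the pull-down. MSTRG.35394.9 was at 1.11 ± 1.19 TPM in flow-through and 6.06 ± 3.47 in pull-down, MSTRG.35394.10 at 4.01 ± 1.51 and 0.896 ± 1.38, and MSTRG.35394.8 at 7.39 ± 0.847 and 2.51 ± 4.35. None of the 3 passed the limma threshold (adjusted p 0.150, 0.150 and 0.205), though without pull-down replicate 1 all 3 did where the filter was applied again (0.0460, 0.0207 and 8.27e-04). With the tested transcripts kept, MSTRG.35394.10 and MSTRG.35394.8 passed and MSTRG.35394.9 did not.

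Transcript levels were higher in wild type than in flow-through for 183 of the 210 called transcripts. Lower depth of the flow-through libraries would lose low transcripts but leave the TPM of high ones in place. The answer depended on the group by which high transcripts were chosen. The 10 with a mean of at least 5 TPM in the pull-down, which is in neither compared group, had a median log2 difference of 1.65 (95% bootstrap interval -0.77 to 2.47). The 17 so chosen by flow-through gave -0.13 (-1.65 to 1.56) and the 56 chosen by wild type 3.09 (2.43 to 3.42), choices that favour one side. Lower depth is therefore neither shown nor excluded. Another candidate explanation is that the table lists transcripts chosen for being seen in wild type, since 2.37% of them were at 0 in all 3 wild-type libraries and 49.4% in all 3 flow-through libraries. A true difference would give the same shares, so these cannot be told apart from the listed transcripts alone. Age, injection and fraction, which the design names, remain open and untested.

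The col7a1l transcripts moved in opposite directions between pull-down and flow-through while sharing a last exon. Their reads may have been assigned to one transcript in one group and to the other in the other group. The summed TPM of the 3 col7a1l transcripts in the table differed by 0.22 on the log2 scale, with 17.7 ± 3.05 TPM in flow-through and 20.6 ± 1.85 in pull-down (SD, n = 3 each), as that explanation needs. A switch between forms on ribosomes would leave the same sum and remains open, untested.

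Many events had a PSI of 0 beside a transcript that was well expressed. In wild type, 50.6% of the 166 values at 5 TPM or more had a PSI of 0, which argues against too few reads as the whole cause, although no read numbers were used. A fixed property of the event, such as how the PSI was defined for it, was a candidate explanation. Of 39 events with at least 5 TPM in all 3 wild-type libraries, 15 had a PSI of 0 in all 3 libraries, 16 in none and 8 (20.5%) in some. Zeros thus mostly recurred in the same events, which argues against sampling that strikes all events alike. The 20.5% lay between the bounds set in advance. Sampling at a rate that differs between events could also recur, so it cannot be told apart from a fixed property. No biological explanation was tested.

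Pull-down and wild type may share differences from the flow-through. Over 296 transcripts the covariance of the differences was 0.410, against 0.110 added by the shared flow-through libraries (simulated 0.110), an excess of 0.300 (95% bootstrap interval 0.113 to 0.534), or 0.162 (0.0516 to 0.279) without the 4 called transcripts. Both intervals come from resampling transcripts, which share the same libraries, so they do not measure the spread between libraries. Pearson's r, across transcripts that are not independent replicates, was 0.358, and 0.520 in a simulation with no effect. That simulation lacks the real differences, which widen the spread by which r is scaled, so these r values cannot be compared.

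The width of the last exon was set against the pull-down difference over the 132 tested transcripts. Spearman's rho across transcripts was 0.119 (95% bootstrap interval -0.0379 to 0.280, permutation p 0.173). The bound set in advance was met by rho and not by its interval, so a weak relation is not excluded. Pearson's r on the log2 width was 0.107 (permutation p 0.222), and 0.106 without the 2 widths farthest from the median. The number of events with PSI above 0 had a mean difference of -28.7, pull-down minus flow-through (67.7 ± 35.8 against 96.3 ± 28.0, SD, n = 3 each), and the libraries overlapped (exact permutation p 0.2), which with 3 against 3 libraries neither shows nor excludes a difference.

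With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For pull-down against flow-through, 1 split gave as many transcripts as the real 4, the real one included (highest other 1), and 3 splits gave as many events as the real 2 (highest other 2). For wild type against flow-through, 1 split reached the real 210 transcripts (highest other 0) and 1 the real 36 events (highest other 2). For pull-down against wild type, 1 split reached the real 186 transcripts and 1 the real 34 events (highest other 0 for each).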
